A study of Mus musculus with 6 samples.

How the data were processed

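Total RNA of B16F10-OVA cells was depleted of rRNA and made into strand-specific libraries for Illumina sequencing, per the labels' protocols. 6 libraries were analysed, 3 from untreated cells and 3 from cells treated with 50 µM Ac4ManNAz for 5 days and passaged on day 3, and groups and replicate numbers were taken from the sample titles. The authors deposited a single table of FPKM, a fragment value scaled for transcript length and library depth, with 1 value per annotated transcript and library. The unit was taken from the name of the deposited table and from its values, which were not whole and whose sums differed between libraries. The aligner, quantifier, their versions, the genome build and the annotation release are not given in the sources used here. Coordinates are printed as deposited, 1-based, and their build is likewise not given in the sources used here. Of 58441 transcripts whose identifiers occur in the GENCODE M21 annotation of GRCm38, 98.8% have the same span there but 2.2% start at the same position, so GRCm38 coordinates were not used. The ovalbumin transgene was not analysed here.

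The 59192 transcripts were summed to 21801 genes by the gene names and identifiers of the table. FPKM values are not counts, so no count test was used. Values were taken to log2(FPKM + 1), and the 9925 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), treated minus untreated, with group as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The same test was run on the 14846 transcripts with a mean of at least 1 FPKM. Genes whose 95% moderated confidence interval lay between -1 and 1 on the log2 scale were counted as within 2-fold. Tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

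37 gene lists were written from general knowledge of the compound, the cell line and common stress responses, including markers of 5 other cell types. Of their 1121 symbols, 4 were not matched to the table. The 32 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with fry's directional test and with a rank version of camera. Members were also adjusted over the list alone. The mean level of each list was compared between groups by an exact two-sided permutation test.

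Genes were named by a fixed rule. Where fewer than 10 genes passed in a direction, up to 5 genes with the smallest unadjusted p were named in that direction and said not to pass. Gne, Nans, Nanp, Cmas, Slc35a1, Nagk, Mitf, Tyr, Pmel and Dct were named in any case. The 3 members with the smallest p were named for each list that passed, and the 2 members with the smallest p for the lists of sialyltransferases, hexosamine and O-GlcNAc, glycocalyx core proteins, adhesion receptors and the unfolded protein response. A result of 1 gene that this rule takes is not reported here. Other genes named in the text were chosen after their values were seen, as members of a short count or as single features.

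The groups, the tests, the lists, the rule for named genes and most alternative settings were chosen before the data were examined. The alternatives were another pseudocount (0.1), no filter and a stricter one (mean FPKM of at least 5), 4 other scalings, eBayes without trend or with robust estimation, sample quality weights, the replicate number as a block, the most abundant transcript in place of the gene sum, other thresholds, and each library left out in turn. Chosen after the data were seen were a covariate for the signal over olfactory receptor genes, the removal of genes that a library lists under 0.1 of their median, and the restriction to transcripts above 0 in all libraries.

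The table holds no counts. Among genes with 1 transcript, the most common low value of FPKM times length was taken as the step of 1 fragment. It implied 30100000 to 45600000 fragments per library. In each library 23.5% to 51.9% of low values lay within 2% of that value, where an even spread gives 2.96% to 3.14%. The value was picked as the most common, so an excess there was given in advance and does not test the step. Multiples of it were not looked at. Whole fragments were not recovered, and no counting interval is given. A gene listed at 0 or near 0 is described as listed, since Gapdh, a gene of glycolysis that cells use throughout, was listed between 0.14 and 10.4 FPKM. The gene test was checked by shifting the treated values of 200 of the 9925 genes in the real table, in 20 draws. Shifts of 1.5-, 2- and 4-fold, upward and downward, were mixed in each draw. The median and the highest number of unshifted genes called in a draw were both 3. All draws started from the same real values, so they are not independent checks of false calls. The list test was run on 100 random lists of 30 genes. Without a shift 6 had a camera p under 0.05, and with a shift of 1.2-fold 100 did. Random lists do not test how often camera at a preset 0.01 falsely calls lists whose members vary together. The lists that passed camera had estimated correlations of 0.091 to 0.655.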

Results

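Gene expression was measured in B16F10-OVA cells, a pigmented mouse melanoma line that carries an ovalbumin transgene. Ac4ManNAz is a peracetylated, azide-bearing analog of N-acetylmannosamine, the sugar from which cells make sialic acid. Cells that take it up display azido sialic acids, which can be tagged by click chemistry. 3 libraries came from cells grown with 50 µM Ac4ManNAz for 5 days, with a passage on day 3, and 3 libraries came from untreated cells. The design holds a single comparison, treated against untreated, which asks how far the labelling itself alters the transcriptome. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

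The libraries listed 13912 to 18974 genes above 0 FPKM and 9678 to 10042 genes at 1 FPKM or more. The most common low value of FPKM times length implied 37400000, 45600000 and 30100000 fragments in untreated replicates 1 to 3. It implied 36100000, 32300000 and 34600000 in treated replicates 1 to 3, if that value stands for 1 fragment. The melanosome genes Pmel and Tyrp1 were among the 20 most abundant genes, which together held 12.6% to 13.9% of the summed FPKM. Treated and untreated libraries were as similar to each other as libraries of the same group. Pearson's r across the 9925 tested genes averaged 0.969 between groups (range 0.960 to 0.975) and 0.966 within groups (range 0.959 to 0.974). Genes are not independent replicates, so these coefficients carry no p-value.

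After 5 days of Ac4ManNAz, gene levels differed little from those of untreated cells for most genes, and no single gene passed the test. The median absolute log2 difference was 0.10, and the other 9 splits of the 6 libraries into groups of 3 gave 0.08 to 0.15. For 9030 of the 9925 genes, or 91%, the 95% confidence interval of the difference lay within 2-fold in either direction, and for 6384 genes, or 64.3%, it lay within 1.5-fold. The share within 2-fold was 82.9% with a pseudocount of 0.1 and 79.8% with the most abundant transcript of each gene in place of the sum. Differences are on the log2(FPKM + 1) scale, which understates those of low genes, and intervals are per gene, not adjusted for the number of genes. The melanosome gene Pmel averaged 4312 ± 442 FPKM in untreated and 4381 ± 535 in treated cells (mean ± SD, n = 3 in each group, as for all such values).

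limma with Benjamini-Hochberg adjustment called 0 of the 9925 genes, and therefore 0 genes at 2-fold or more, and the smallest adjusted p was 0.9998. An unadjusted p under 0.05 was reached by 177 genes, 87 higher and 90 lower in treated cells, where chance gives 496. This count depended on single libraries, from 120 without untreated replicate 2 to 459 without untreated replicate 1 and 532 without Ac4ManNAz replicate 1. The 3 treated values lay all above the 3 untreated values for 208 genes and all below for 368, together 5.8% of genes, where chance gives 10%. With sample quality weights limma called 2 genes, Arhgap27 and Slc6a17. With the most abundant transcript of each gene in place of the gene sum it called 4 genes, P3h1, Stk11, Tubgcp5 and 9530068E07Rik. These calls rest on single transcripts that are among the called transcripts described below. In each of these genes another transcript moved the other way, by 2.01, 1.01, -1.61 and -4.63 on the log2 scale. Without Ac4ManNAz replicate 2 it called 1 gene, Ube2v2. This gene was listed at 18.3, 13.6 and 26.9 FPKM in the untreated and 0.028, 11.3 and 0 FPKM in the treated libraries. The library left out was thus the only treated one near the untreated level. With shifts put into the real values, the test recovered 3.8% of genes shifted 1.5-fold, 36% of those shifted 2-fold and 78.6% of those shifted 4-fold. The 3 shifts were mixed in each draw, so recovery of the smaller ones may be lower where they occur alone.

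**Figure D1:**
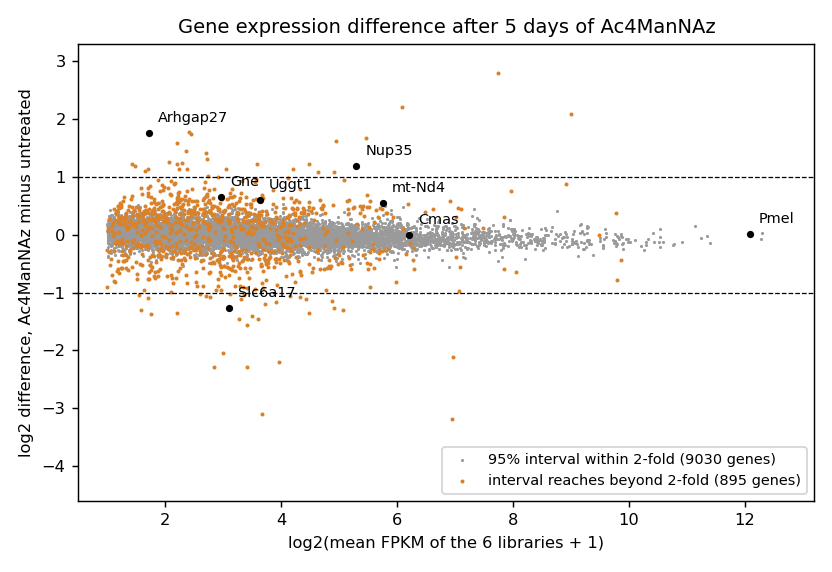
Difference between treated and untreated cells (log2 of FPKM + 1, treated minus untreated) against mean level for the 9925 tested genes, 1 point per gene. Grey points are the 9030 genes whose 95% confidence interval lay within 2-fold (dashed lines), orange points are genes whose interval reached further, and black points are genes named in the text, none of which passed the adjusted test.

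The genes with the smallest unadjusted p-values are given here although they did not pass. Among those that averaged higher in treated cells, Arhgap27, a GTPase-activating protein (ENSMUSG00000034255, chromosome 11, 103222323 to 103254290), had 0.454 ± 0.215 FPKM in untreated and 4.10 ± 1.66 in treated cells, a log2 difference of 1.77 ± 0.27 (SE). Coa7, a mitochondrial protein needed for cytochrome c oxidase assembly, had 0.971 ± 0.133 and 3.27 ± 0.725 FPKM. The nuclear pore gene Nup35 had 23.1 ± 6.60 and 53.6 ± 11.7 FPKM, and Taf1d, a subunit of the RNA polymerase I promoter complex, had 6.07 ± 0.816 and 16.0 ± 5.82 FPKM. Uggt1, the sensor of misfolded glycoproteins in the endoplasmic reticulum (chromosome 1, 36179108 to 36283386), had 8.82 ± 0.174 FPKM in untreated and 13.9 ± 1.66 in treated cells, a log2 difference of 0.60 ± 0.12.

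Among the genes that averaged lower, the amino acid transporter Slc6a17 (ENSMUSG00000027894, chromosome 3, 107374859 to 107425334) had 11.1 ± 0.776 FPKM in untreated and 4.08 ± 0.959 in treated cells, a log2 difference of -1.26 ± 0.16. Mtif3, a mitochondrial translation initiation factor, had 12.2 ± 1.29 and 6.14 ± 1.51 FPKM. The kinase gene Stk11, which encodes LKB1, had 7.14 ± 1.04 and 3.42 ± 0.876 FPKM. Tg, the thyroglobulin gene, had 34.8 ± 2.47 and 25.2 ± 1.30 FPKM, and the centriole gene Odf2 had 14.2 ± 1.59 and 9.38 ± 0.690 FPKM. For these 10 genes the treated values lay all on 1 side of the untreated values, and the unadjusted limma p ranged from 0.000111 for Slc6a17 to 0.00349 for Odf2.

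The enzymes through which the analog enters sialic acid synthesis were next compared. Gne, the rate-limiting enzyme of natural sialic acid synthesis (ENSMUSG00000028479, chromosome 4, 44034075 to 44084177), averaged 4.97 ± 1.59 FPKM in untreated and 8.69 ± 3.96 in treated cells, with overlapping libraries. Its log2 difference of 0.66 had a 95% interval from -0.09 to 1.41. Nans, the sialic acid synthase, had 42.3 ± 4.36 and 42.3 ± 3.65 FPKM, and Cmas, which activates sialic acid to its CMP form, had 72.8 ± 5.90 and 72.6 ± 3.27 FPKM. Slc35a1, which carries CMP-sialic acid into the Golgi, had 22.5 ± 1.25 and 22.2 ± 0.647 FPKM. For Nans, Cmas and Slc35a1 the 95% intervals lay between -0.28 and 0.28 on the log2 scale. Nagk, a kinase of N-acetylglucosamine, had 19.04 ± 6.403 and 22.1 ± 7.98 FPKM. Nanp, the phosphatase that completes sialic acid synthesis, was listed at 2.95, 3.18 and 0 FPKM in the untreated libraries and at 4.15, 3.61 and 3.19 FPKM in the treated ones. Of the 11 tested genes of sialic acid metabolism, 7 averaged higher and 4 lower, and 0 passed over all genes or adjusted over the list alone.

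**Figure D2:**
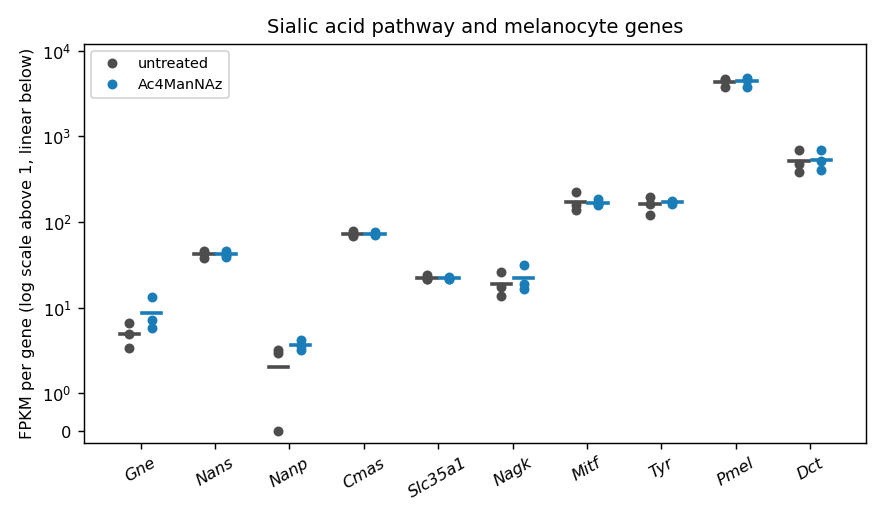
FPKM per gene in each library for genes of the sialic acid pathway (Gne to Nagk) and of melanocyte identity (Mitf to Dct), with 3 untreated (grey) and 3 treated (blue) libraries as points and group means as bars. The axis is logarithmic above 1 FPKM and linear below. Nans, Cmas and Slc35a1 had nearly equal means in both groups, and Nanp was listed at 0 in untreated replicate 3.

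Gene groups that build or display glycans showed no shift that passed. Among 10 sialyltransferases, 6 averaged higher and 4 lower: St3gal1 had 19.6 ± 0.75 FPKM in untreated and 24.1 ± 3.13 in treated cells, though its most abundant transcript went the other way, and St6galnac4 had 8.02 ± 0.513 and 6.12 ± 2.26 FPKM. Of 15 genes of the hexosamine pathway and O-GlcNAc cycling, 6 averaged higher. The glucosamine-6-phosphate deaminase genes Gnpda2 (8.84 ± 0.752 and 10.7 ± 0.368 FPKM) and Gnpda1 (14.4 ± 5.19 and 10.2 ± 4.91 FPKM) had the smallest p-values in that list. Of 17 cell-surface mucins, proteoglycans and sialylated glycoproteins, 11 averaged higher, with L1cam at 2.68 ± 0.860 and 4.43 ± 1.503 FPKM and Cd47 at 5.74 ± 1.81 and 7.64 ± 0.861 FPKM. Of 19 adhesion receptors, 12 averaged higher, with Itgav at 7.70 ± 1.66 and 12.6 ± 6.38 FPKM and Jam3 at 10.9 ± 0.298 and 9.89 ± 0.751 FPKM. Of 27 chaperones and targets of the unfolded protein response, 18 averaged lower, with Hyou1 at 47.3 ± 4.89 and 40.7 ± 4.01 FPKM and Creld2 at 59.2 ± 4.96 and 51.4 ± 7.37 FPKM. Adjusted p-values for these lists and for sialic acid metabolism ran from 0.158 to 0.813 with limma's camera and Benjamini-Hochberg adjustment over the 32 lists tested, and 0 members passed over all genes or adjusted over the list alone.

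Mitf, Tyr, Pmel and Dct, the melanocyte identity genes fixed beforehand, had similar mean levels with and without the analog. Mitf, the master regulator of the lineage, had 172 ± 44.5 FPKM in untreated and 167 ± 14.6 in treated cells. Tyr, the rate-limiting enzyme of melanin synthesis, had 161 ± 38.8 and 170 ± 7.43 FPKM, and the melanin synthesis gene Dct had 519 ± 163 and 537 ± 147 FPKM. The 95% intervals of these 3 genes and of Pmel lay within 2-fold. Other members of the list, chosen after their values were seen, were bounded less closely. Mlana had a log2 difference of -0.78 with a 95% interval from -2.48 to 0.92, and Oca2, a melanosomal transport gene, averaged 12.1 ± 5.22 and 5.19 ± 6.09 FPKM, a log2 difference of -1.46 with an interval from -2.96 to 0.04. Of 22 melanocyte genes, 14 averaged lower and 8 higher, with a camera adjusted p of 0.629.

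7 of the 32 gene lists passed limma's camera test with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment, 3 upward and 4 downward, and 0 of the 7 passed with an estimated correlation. Of the protein-coding genes of the mitochondrial genome, 12 of 13 averaged higher in treated cells, with a mean log2 difference of 0.25 and a camera adjusted p of 7.79e-07. With an estimated correlation this list had p = 0.0359 and an adjusted p of 0.998. mt-Nd4 had 42.6 ± 2.54 FPKM in untreated and 63.7 ± 12.5 in treated cells, mt-Nd5 had 55.8 ± 6.65 and 79.2 ± 13.7 FPKM, and mt-Cytb had 135 ± 23.8 and 185 ± 21.1 FPKM. Of the G1/S and DNA replication genes, 31 of 35 averaged lower by a small amount, with a mean log2 difference of -0.11 and a camera adjusted p of 0.000154. With an estimated correlation that list had p = 0.0644 and an adjusted p of 0.998. Mcm3, a subunit of the replicative helicase, had 81.6 ± 6.75 and 69.7 ± 4.31 FPKM, the thymidylate synthase gene Tyms had 22.9 ± 3.20 and 18.1 ± 3.14 FPKM, and Uhrf1, which couples replication to DNA methylation, had 113 ± 4.84 and 100.04 ± 7.13 FPKM. With limma's directional fry test and Benjamini-Hochberg adjustment, the G1/S list had an adjusted p of 0.480 and the mitochondrial list an adjusted p of 0.978.

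These were the 2 lists whose mean level separated the 3 treated from the 3 untreated libraries, for the mitochondrial list only narrowly. On that list untreated replicate 1 stood at 0.0514 and Ac4ManNAz replicate 3 at 0.0586 (log2). Relative to the mean of all libraries, the mitochondrial list stood at -0.12 ± 0.16 in untreated and 0.12 ± 0.06 in treated cells (log2), and the G1/S list at 0.05 ± 0.01 and -0.05 ± 0.02. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow. Mitochondrially encoded genes held 1.43% to 2.15% of the summed FPKM in untreated and 1.77% to 1.97% in treated libraries, so that share did not separate the groups.

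4 of the other lists that passed camera contained cell growth or stress genes whose libraries overlapped between groups. Of the G2/M and mitosis genes, 29 of 35 averaged lower (mean log2 difference -0.07, camera adjusted p 0.0135; with an estimated correlation p = 0.362, adjusted p 0.998), with Kif2c at 25.2 ± 1.44 and 21.8 ± 1.90 FPKM, Aurka at 51.9 ± 7.04 and 44.0 ± 4.84 FPKM, and Cdk1 at 50.01 ± 6.95 and 43.8 ± 2.81 FPKM. Of the cytosolic ribosomal protein genes, 65 of 77 averaged lower (-0.08, camera adjusted p 0.000318, but p = 0.465 and adjusted p 0.998 with an estimated correlation). Rpl24 had 624 ± 33.9 and 487 ± 90.8 FPKM. Rps27a went against its list, at 33.1, 292 and 7.996 FPKM in the untreated and 339, 320 and 279 FPKM in the treated libraries. Rpl10a stood at 377 FPKM in untreated replicate 3 and between 61.8 and 109 FPKM in the other libraries. Of the replication-dependent histone genes, 45 of 52 averaged lower (-0.18, camera adjusted p 0.000222, but p = 0.371 and adjusted p 0.998 with an estimated correlation). H2ac7 had 334 ± 19.8 and 252 ± 31.9 FPKM, and H2bc13 had 14.95 ± 4.88 and 5.68 ± 3.87 FPKM. H3c14 was listed at 171, 182 and 177 FPKM in untreated and at 0.014, 44.8 and 158 FPKM in treated libraries. Histone and ribosomal protein genes have near-identical copies and pseudogenes, so the levels of single members are uncertain. Of the NRF2 targets and antioxidant enzymes, 24 of 30 averaged higher (0.13, camera adjusted p 0.0422, but p = 0.432 and adjusted p 0.998 with an estimated correlation). The NRF2 list lost its call under 10 of 22 alternatives. The glutathione transferase gene Gstp1, which also has a close paralog, had 371 ± 69.9 and 492 ± 106 FPKM, and the antioxidant enzyme genes Prdx6 and Sod1 had 37.1 ± 11.3 and 26.5 ± 6.68, and 66.7 ± 9.13 and 74.7 ± 6.35 FPKM.

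The list of interferon-stimulated and antigen presentation genes also passed camera, with 25 of 30 members averaging higher (mean log2 difference 0.23, camera adjusted p 0.00234, but p = 0.416 and adjusted p 0.998 with an estimated correlation). Tapbp, which loads peptides on class I molecules, had 4.08 ± 1.78 FPKM in untreated and 6.46 ± 1.26 in treated cells, and the transcription factor gene Irf1 had 5.72 ± 1.12 and 4.24 ± 0.637 FPKM. The list level ranged from -0.66 to 0.36 among the untreated and from -0.30 to 0.50 among the treated libraries. With fry and Benjamini-Hochberg adjustment, the G2/M, ribosomal protein, histone, NRF2 and interferon lists each had an adjusted p of 0.978. In the 7 lists 0 members passed over all genes or adjusted over the list alone. These 5 lists lost the call when single libraries were left out: the G2/M list without untreated replicate 2, Ac4ManNAz replicate 1 or Ac4ManNAz replicate 2 (limma camera adjusted p up to 0.961), ribosomal proteins without untreated replicate 2, Ac4ManNAz replicate 2 or Ac4ManNAz replicate 3 (up to 0.582), histones without untreated replicate 3 or Ac4ManNAz replicate 2 (up to 0.926), NRF2 targets without untreated replicate 2, untreated replicate 3 or Ac4ManNAz replicate 2 (up to 0.956), and interferon genes without untreated replicate 3 or Ac4ManNAz replicate 2 (up to 0.832). The number of lists that passed was 2 without Ac4ManNAz replicate 2, namely the mitochondrial and G1/S lists, 4 without untreated replicate 2 and 11 without untreated replicate 1.

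**Figure D3:**
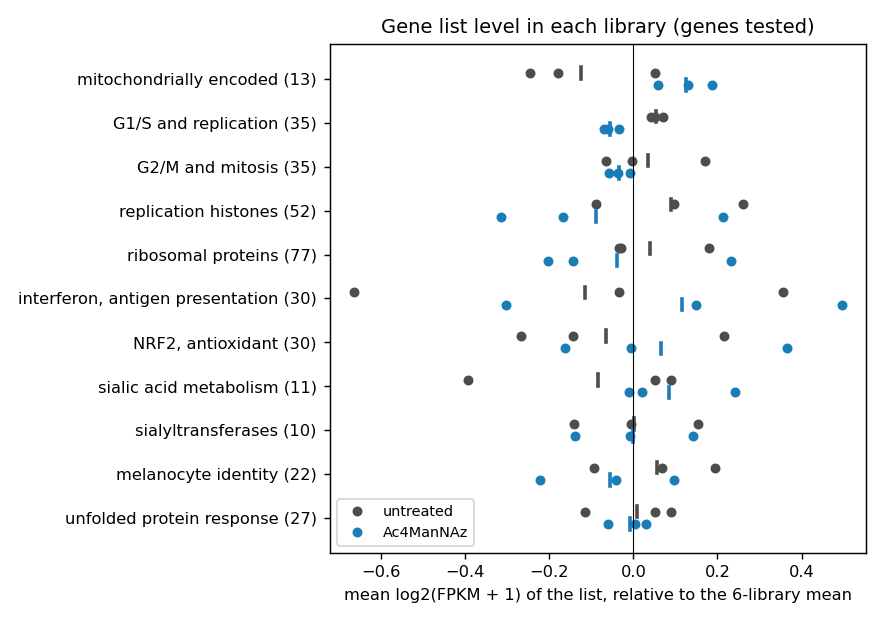
Mean log2(FPKM + 1) of the tested members of 11 gene lists in each library, relative to the mean of the 6 libraries, with the number of members in parentheses, untreated libraries in grey, treated libraries in blue and group means as bars. The treated libraries stood apart from the untreated ones for the G1/S list and narrowly for the mitochondrially encoded list. On the latter, untreated replicate 1 stood at 0.0514 and Ac4ManNAz replicate 3 at 0.0586. Untreated libraries alone ranged from -0.66 to 0.36 for the interferon list.

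The other 25 lists did not pass camera, with adjusted p-values from 0.142 upward. Among stress responses, 14 of 16 hypoxia targets and 19 of 28 ATF4 targets averaged higher, each list with an adjusted p of 0.142, as did 17 of 24 p53 targets (0.296), 24 of 34 lysosome and autophagy genes (0.158), 8 of 15 cytosolic heat shock genes (0.987), 4 of 7 NF-kB targets (0.920) and 9 of 17 immediate early genes (0.630). Among metabolic lists, 24 of 68 nuclear-encoded respiratory chain genes averaged higher (0.629), as did 10 of 24 sterol synthesis genes (0.793), 9 of 24 acetate and fatty acid genes (0.987) and 9 of 18 glycolysis genes (0.997). Among glycan and secretory lists, 19 of 38 N-glycosylation genes (0.630), 7 of 13 O-glycosylation genes (0.984), 19 of 29 glycosaminoglycan genes (0.523) and 14 of 35 Golgi genes (0.975) averaged higher. Among adhesion and matrix lists, 16 of 19 matrix genes (0.158), 14 of 27 focal adhesion and YAP target genes (0.984) and 8 of 14 mesenchymal transition genes (0.984) averaged higher. 7 of these lists passed camera when a single library was left out: ATF4 targets (limma camera adjusted p 0.00268), hypoxia targets (0.00513), lysosome genes (0.00145) and p53 targets (0.00128) without untreated replicate 1, ATF4 (0.0197), hypoxia (0.0217) and p53 targets (0.0470) without Ac4ManNAz replicate 3, sterol synthesis genes without untreated replicate 3 (0.0392) or Ac4ManNAz replicate 1 (0.000691), and matrix (0.00762) and nuclear-encoded respiratory chain genes (0.00288) without Ac4ManNAz replicate 1. In each of these lists 0 members passed over all genes or adjusted over the list alone. The mean, the median and the direction of the test did not all have the same sign for the lists of sialyltransferases, N-glycosylation, O-glycosylation, mesenchymal transition, focal adhesion, heat shock, acetate and fatty acid, and glycolysis genes.

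Markers of other cell types were low in both groups. The lists of fibroblast, leukocyte, endothelial, keratinocyte and erythroid markers had too few tested members for a test. Their tested members were the collagen gene Col1a2 among 12 fibroblast markers (3.18 ± 0.312 FPKM in untreated and 2.77 ± 1.52 in treated cells), Cd68 (1.15 ± 0.305 and 1.52 ± 0.640 FPKM) and Lyz2 (2.71 ± 1.03 and 2.93 ± 1.12 FPKM) among 20 leukocyte markers, and Egfl7 (6.05 ± 1.01 and 6.78 ± 0.861 FPKM) and Vwf (1.77 ± 0.831 and 1.95 ± 0.787 FPKM) among 14 endothelial markers. The remaining markers of these lists, including all 15 keratinocyte and 9 erythroid ones, reached at most 1.40 FPKM in any library.

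Single transcripts passed the test although no gene sum did. 9530068E07Rik-202 was listed at 0.169, 0.107 and 0.171 FPKM in the untreated and 55.9, 65.9 and 57.8 FPKM in the treated libraries. The other transcript of the same gene, 9530068E07Rik-201, was listed at 63.7, 63.1 and 44.9 FPKM in the untreated and 1.08, 1.11 and 1.83 FPKM in the treated libraries. The gene sum of 9530068E07Rik differed by 0.11 on the log2 scale. P3h1-202, from the gene of a collagen prolyl hydroxylase, was listed at 12.4, 11.99 and 14.7 FPKM in untreated libraries and at 0 in the 3 treated ones. Stk11-201 was listed at 5.24, 6.85 and 6.92 FPKM in untreated and 0.622, 0.442 and 0.536 FPKM in treated libraries, and the Stk11 gene sum also averaged lower.

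limma with Benjamini-Hochberg adjustment called 9 of 14846 transcripts in 8 genes, 4 higher and 5 lower, and 377 had an unadjusted p under 0.05. Splits that mixed treated and untreated libraries called 8 to 33 transcripts. The other called transcripts were Tubgcp5-205, Ints10-203 and Sanbr-202, which were higher in treated cells, and Ube2v2-203 and Tepsin-201, which were lower. Tubgcp5-205 and Sanbr-202 were listed at 0 in all 3 untreated libraries, and Tepsin-201 in all 3 treated ones. The median absolute log2 difference was 2.96 for the 9 transcripts, which were selected by passing, and 0.37 for the sums of their genes. The count of called transcripts was 1 with the replicate number as a block, 2 at a mean of at least 5 FPKM, 4 with the background covariate, 4 with transcripts above 0 in all libraries, 15 without trend and 19 with sample quality weights, and leaving out a library gave 4 to 14, with 4 without untreated replicate 3 or Ac4ManNAz replicate 2, 5 without Ac4ManNAz replicate 3 and 14 without untreated replicate 2.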

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

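The background covariate, the removal of genes listed low in a library and the restriction to transcripts above 0 in all libraries were chosen after the data were seen. The count of changed genes, 0, was also 0 under the alternatives tried, other adjusted p thresholds included, except 2 with sample quality weights, 4 with the most abundant transcript and 0 to 1 when a library was left out (1 without Ac4ManNAz replicate 2). Genes changed at least 2-fold followed the same counts: 2, 4 and 0 to 1. Sample quality weights gave Ac4ManNAz replicate 3 a weight of 6.07 and the other libraries 0.371 to 2.89, and 2389 genes then had an unadjusted p under 0.05. The number of genes within 2-fold was 9030, 19270 of 20352 without a filter, since more genes were tested, and 8612 to 8817 when a library was left out. As a share of genes it was lower with a pseudocount of 0.1 (82.9%) and with the most abundant transcript (79.8%) than the 91% reported. The 9 called transcripts became 2 at a mean of at least 5 FPKM, 15 without trend, 19 with sample quality weights and 4 with the background covariate. They became 4 with transcripts above 0 in all libraries, and 4 to 14 when a library was left out. The filters take some of the 9 out of the test, and causes beyond that were not tested. The 7 gene lists became 0 with an estimated correlation and 0 with fry, which allow for members that vary together, and 2 to 11 when a library was left out. The G1/S list passed under 20 of 22 alternatives (mean log2 difference -0.15 to -0.06) and the mitochondrial list under 19 of 21 (0.19 to 0.34), both lost with an estimated correlation and fry. The G2/M list passed under 15, ribosomal proteins under 16, interferon genes under 17, NRF2 targets under 12 and histones under 18 of 22, and the histone list had an adjusted p of 1.52e-11 to 0.926 when a library was left out, its test turned to the other direction without Ac4ManNAz replicate 2 (adjusted p 0.871) although its mean log2 difference stayed negative (-0.33 to -0.07). The mean log2 difference crossed 0 for interferon genes (-0.05 to 0.47), NRF2 targets (-0.02 to 0.27) and ribosomal proteins (-0.30 to 0.005), and reached from -0.15 to -0.0008 for the G2/M list. Of the 549 values of the lists that did not pass, 77 changed sign, so the numbers of their members that averaged higher set no direction, and 7 lists passed in 16 values, among them ATF4 targets and lysosome genes with quantile normalization, lysosome genes with the most abundant transcript and nuclear-encoded respiratory chain genes with sample quality weights. Among the values of the 51 genes that the naming rule takes under these settings, 33 of 1009 changed sign, in 10 genes that did not pass under either setting (Cmas, Slc35a1, Mitf, Nans, Nagk, Pmel, Tyr, Dct, Sod1 and St3gal1), so no direction is given for them. For St3gal1 the most abundant transcript gave -1.03. Camera has no robust form, so that setting gave no list result. With the replicate number as a block, 0 genes, 1 transcript and 7 lists were called and 9163 genes lay within 2-fold. 6 of these lists were among those reported, whereas the NRF2 list lost its call and hypoxia targets passed instead (adjusted p 0.0267). The labels do not tie equal numbers together, so the numbers were not taken as a pairing. Deviations of libraries with the same number correlated at 0.06, 0.02 and 0.26. Libraries of different group and number gave -0.174 to 0.084. The value of 0.26 lay above that range, so these few values do not exclude a pairing. Depth is known only as implied by the most common low value of FPKM times length. When shifts of mixed size were put into the real values, 36% of 2-fold and 78.6% of 4-fold shifts were recovered.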

Other observations

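The tests of members that vary together and of the number of fragments sequenced were chosen only after the results were seen, and the genes singled out here were chosen after their values were seen. The tests of scaling, of genomic DNA and of treatment as a source of low signal also address patterns first seen in these data. Of the genes that make sialylated surfaces, these cells expressed St3gal4 at 64.4 ± 6.69 FPKM in untreated and 56.3 ± 9.69 in treated cells, St3gal6 at 45.6 ± 8.68 and 42.9 ± 10.4, and St6galnac6 at 31.0 ± 2.61 and 33.0 ± 2.84 (mean ± SD, n = 3 in each group), while St6gal1 stood at 7.47 ± 3.11 and 7.44 ± 1.53. Among carriers of sialylated glycans, Lamp1 had 319 ± 17.3 and 321 ± 14.2 FPKM, the immunoglobulin-family protein gene Bsg had 277 ± 45.0 and 293 ± 60.3, the hyaluronan receptor gene Cd44 had 141 ± 11.7 and 140.3 ± 12.7, and the glypican gene Gpc1 had 132 ± 15.4 and 146 ± 30.2. None of these genes passed the gene test.

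The N-glycosylation list did not pass, and of its 38 members 19 averaged higher and 19 lower. Its mean log2 difference was 0.05 and its median -0.0036. Within this list 4 members had an unadjusted limma p under 0.05, and all 4 averaged higher in treated cells. They were picked by their p-values and set no direction for the list. Besides Uggt1 these were the mannosyltransferase gene Alg9 (8.71 ± 1.86 and 14.7 ± 3.44 FPKM), the glucosyltransferase gene Alg6 (3.11 ± 1.43 and 5.90 ± 1.51 FPKM) and the Golgi mannosidase gene Man2a2 (12.5 ± 0.773 and 15.3 ± 0.599 FPKM). Adjusted over the list alone with the Benjamini-Hochberg method, the limma p-values were 0.0692 for Uggt1, 0.288 for Alg9 and 0.313 for Alg6 and Man2a2. Trib3, an ATF4 target, had 4.15 ± 1.34 and 7.09 ± 0.641 FPKM, with all treated libraries above the untreated ones, and did not pass either (0.311 over its list).

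The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, 0 at 2-fold or more, and the highest of the other splits called 8 and 7. On both counts 10 of the 10 splits gave as many, which was given in advance, since no split can call fewer than 0. It left 9030 genes within 2-fold and the lowest of the others left 8838, with as few or fewer in 8 of the 10 splits. It called 9 transcripts against at most 33, with as many in 9 of the 10 splits, and 7 lists against at most 11, with as many in 7. Of the 10 splits, the real one included, camera called ribosomal proteins in 8, histones in 7 and interferon genes in 6. The G2/M and NRF2 lists were called in 5 each, the G1/S list in 3 and the mitochondrial list in 2. These calls thus also arose when treated and untreated libraries were mixed. The real split also had the fewest genes with an unadjusted p under 0.05, 177, but the next split had 185, and 2 other splits had a smaller median absolute log2 difference (0.0841 and 0.0885 against 0.0992). The highest count was 1233, when untreated replicate 1 and Ac4ManNAz replicates 2 and 3 were set against the rest. How far such counts range among correlated genes by chance was not tested, so no structure of the libraries is inferred from them. The first 2 principal components held 29.7% and 27.5% of the variance, and untreated and treated libraries overlapped on both. Of the 5 components only the fourth, with 13% of the variance, held the treated libraries (11, -0.69 and 16.79) apart from the untreated ones (-7.07, -11.59 and -8.43).

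The mitochondrially encoded and the G1/S list were those with the treated libraries apart from the untreated ones, the mitochondrial list only narrowly. For the mitochondrial list the tables argue against scaling of the libraries as the source: under the 3 scalings that keep its genes the mean log2 difference was 0.25 to 0.31, with 0.2527 nearest to 0, against 0.2489 as deposited. For the G1/S list the difference shrank from -0.11 to as little as -0.0636 when libraries were rescaled to the same sum. This lay between the bounds of -0.05 and -0.08 set for the test, which thus cannot decide on scaling. The same rescaling moved the median log2 difference of all tested genes from -0.0014 to 0.0408. Camera, which compares a list with the other genes, kept the G1/S call under all 4 scalings. These values argue against scaling as the source of the list's shift relative to other genes. Members that vary together could also give such a shift. For each list 1 of the 10 splits, the real one, gave an absolute mean difference as large. The next split gave 0.2441 for the mitochondrial list and 0.0591 against 0.109 for the G1/S list. Camera called the mitochondrial list in 2 and the G1/S list in 3 of the 10 splits, the real one included. The adjusted camera p with an estimated correlation was 0.998 for both. An effect of Ac4ManNAz on mitochondrial transcripts and replication genes therefore stays open as a hypothesis.

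The cause of the differences of the 9 called transcripts stays unknown. Splits that mixed treated and untreated libraries called 8 to 33 transcripts, so a count of 9 does not tie the calls to the treatment. A comparison with their gene sums was looked at and does not tell causes apart, since the transcripts were picked for their differences and a real switch between transcripts leaves gene sums as close as an uneven assignment of fragments. In 9530068E07Rik the 2 transcripts shared the start at 52287255 on chromosome 11 and ended at 52299550 and 52299555, and exchanged nearly all their signal between groups. For Ube2v2, Tubgcp5, Stk11 and Ints10 the gene sums had log2 differences of -3.09, 1.13, -0.89 and 0.40 with an unadjusted limma p under 0.05, and none of them passed the adjusted test.

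Low signal over genes that melanoma cells do not use differed between libraries. Of 1139 olfactory receptor genes, 44.5%, 7.11% and 67.1% were above 0 in the untreated and 7.64%, 28.5% and 76.4% in the treated libraries, at mean levels of 0.00163 to 0.0336 FPKM. Treatment is an unlikely source, since both groups spanned nearly the same range (39.6% ± 30.3 in untreated and 37.5% ± 35.2 in treated libraries, SD, exact permutation p = 1). Whether depth plays a part cannot be told, since depth is only implied by the most common low value and its relation to the share was within chance. Spearman's rho was -0.6 (exact permutation p = 0.242). Pearson's r was -0.608 (exact permutation p = 0.192), and -0.043 without the 2 libraries farthest from the median. Genomic DNA in the RNA is a candidate source: among 15 pairs of 6 silent gene families the 10 pairs without defensins had rho of at least 0.886 for the mean level over the libraries, but the lowest rho, for defensins and vomeronasal receptors 1, was 0.543 (exact permutation p = 0.297, adjusted 0.297; r 0.473, p = 0.336, adjusted 0.338, and -0.512 without 2 libraries), between the bounds of 0.5 and 0.8 set for the test. Single genes can carry such means, since 1 vomeronasal receptor 1 gene in every library and 1 defensin gene in untreated replicate 1 stood above 1 FPKM, and the share of genes above 0, looked at afterwards, ranked the libraries nearly alike in all 15 pairs (rho 0.943 to 1, exact permutation p up to 0.017, adjusted up to 0.017; r 0.936 to 0.998, p up to 0.006, adjusted up to 0.006, and 0.756 to 0.996 without 2 libraries). The families thus varied together, as genomic DNA requires, but their means lay at 0.161 to 2.39 times their median in the libraries with high signal where the test asked for within 2 times, so genomic DNA cannot be told apart from other sources.

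Some abundant genes were listed far lower in single libraries. Of 4767 genes with a median of at least 10 FPKM, 18 had a library under 0.1 of the median, spread over all 6 libraries, and they included Rps27a, H3c14, H2ac18 and Ube2v2. H2ac18 was listed at 1514, 1684 and 0.095 FPKM in the untreated and 1802, 573 and 0.079 FPKM in the treated libraries. Gapdh was listed at 6.20, 0.14 and 0.82 FPKM in the untreated and 0.69, 10.4 and 0.74 FPKM in the treated libraries, whereas Actb had 798 to 1100.2 FPKM. The melanocyte antigen gene Mlana was listed at 158 FPKM in Ac4ManNAz replicate 2 and between 856 and 1269 FPKM in the other libraries.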
